A study of Mus musculus with 4 samples.

How the data were processed

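The authors deposited, per sorted fraction, a matrix made with Cell Ranger 8.0.1 on mm10 with iCre, Cre, hCD2 and tdTomato added as features. Its deposited values are UMI counts per gene or hashtag and barcode, with no normalization and no cell filter, so that all barcodes with a count are present. A deposited table gives the hashtag state of each called cell (a hashtag, Multiplet, Blank or Unassigned) with its posterior probability, a fraction from 0 to 1 made by the multiplexing step of Cell Ranger. The assay was 10x 3' single-cell RNA sequencing of polyadenylated RNA. The hCD2+ library held 178129025 UMIs in 8801 called cells (93.0% of its UMIs) and the hCD2- library 150904166 in 5603 (91.0%).

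Cells with exactly 1 hashtag (7415 hCD2+ and 4907 hCD2-), at least 500 genes and at most 10% mitochondrial UMIs were kept. Multiplets (806 and 465), Blank (295 and 168) and Unassigned (285 and 63) cells were left out of every comparison. Droplets of 10 to 100 UMIs, 151806 and 151362 of them, gave each library's profile of free RNA. Its largest share in a class was taken, after the data were seen, as the lowest ratio of cells to droplets among Cd74, H2-Aa, H2-Ab1, Cd3e, Trac and Itgax, plus 1 SD over mice. Where thinning is named, each cell was sampled down to 5000 UMIs and shallower cells were left out.

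Both libraries were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden, resolution 1.0) on Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9. Genes of the 15 function lists, reporters, sex, cell cycle, ribosomal, mitochondrial, immunoglobulin and hemoglobin genes were kept out of the clustering genes. A cluster took the class of the marker list, of 17, with most markers elevated at least 2-fold and seen in at least 10% of its cells, and needed 3 such markers. The CCR7 list, read as a state, gave way to any other list but that of T cells with at least 5 such markers, as in cluster 23. A cluster got no class if at least 3 T cell markers were elevated beside a class other than T cells, NK or ILC1 and ILC3 or LTi, if its median UMIs were under 1/3 of those of its libraries, or if another list held more of its 10 genes of largest fold. The latter left out cluster 8 (6 of 8 T cell markers) and cluster 25 (9 of 10 CCR7 markers). This naming rule was set after clustering, as were the comparisons of single clusters. Marker lists, function lists, comparisons and the rule for named genes were set before the data were examined. Classes are called "-like" since they rest on transcripts.

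Counts were summed per mouse, fraction and class, with at least 10 cells per mouse (20 for shares), and fitted with edgeR 4.0.16 quasi-likelihood, TMM and filterByExpr in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values in parentheses after a gene are the log2 fold change ± SE, then the number of mice with both arms that show the direction. Levels are CPM (depth-scaled UMI counts), mean ± SD over mice. A gene with 0 counts in an arm has a fold against a floor of 3 counts over the group ("at least"), and one with 1 to 3 counts a ratio of pooled CPM with its 95% counting interval. Gene lists were tested with camera in limma 3.58.1, with an inter-gene correlation of 0.01 and with an estimated one, and adjusted over the lists of a comparison. The central tolerance and epithelial-associated list holds the naming markers Aire, Pigr and Trp63 and too few other tested genes, so that its test between classes was dropped. An added alternative left naming markers out of all lists. Shares were compared by two-sided permutation tests (100000 permutations with at least 10 mice per arm, exact otherwise), adjusted over the classes or clusters tested. For dividing cells a class with under 5 expected in its smaller arm entered that adjustment as not differing, a rule set after the values were seen.

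Genes named per comparison were 2 to 4 per function list (the smallest adjusted p in the direction with more calls, and any against it), and the 10 higher and 10 lower called genes of largest fold change. The latter needed a mean log2 CPM of at least 4 and a common direction in at least 3 of 4 mice with both arms, leaving out predicted models, ribosomal, mitochondrial, immunoglobulin, Y-linked, Xist and Tsix genes, and in class comparisons any clustering gene. Gm38411, Prdm16, Aire, Pigr, Itgb8, Aldh1a2, Ccr7, Zbtb46, Flt3, Il7r and Cd4 could always be named. Results of some other genes are not reported here. Within a class, "clustering gene" marks a gene that helped to make the clusters.

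The same hashtags label the same animals in both libraries. As a check, each mouse's deviation from its fraction's mean over 8804 genes was correlated across genes, which are not independent replicates: r was 0.0367 to 0.452 for equal hashtags (mean 0.294; above 0.1 in 11 of 12) and -0.0267 on average for unequal ones. Xist split the hashtags alike in both libraries for 12 of 12. Paired fits with mouse as a block were therefore run, and are given where they change a call or move a count by more than 1.5 times.

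On counts with simulated changes, edgeR recovered 70 to 92 of 100 genes changed 2-fold over the fits tested, the fewest in Prdm16 or Aire DC against cDC1-like cells and 75 in the interaction, with 3.68% to 7.56% false calls. Paired fits with mouse as a block recovered 64 to 92, with 3.65% to 11.6% false calls. camera called 20 of 20 changed lists. Alternatives were a block for mouse, DESeq2 1.42.0 size factors and Wald tests, no low-count filter, stricter cells (at least 1000 genes, at most 5% mitochondrial UMIs), hashtag probabilities of at least 0.99, at least 20 cells per mouse, thinning, equal cluster mixes, resolutions 0.5 and 1.5, and leaving out genes with a larger share of empty droplets than of cells. Automatic doublet calls by scrublet found 1 of 8801 and 0 of 5603 cells. As an alternative added after the data were seen, cells scoring above the median hashtag multiplet of their library were left out (722 and 147). Plots were drawn with matplotlib 3.10.9.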

Results

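The data were RNA counts of single cells from the mesenteric lymph nodes of 15-day-old Gm38411-iCre-hCD2 R26-tdTomato mice. In these animals a cassette at Gm38411 encodes the iCre recombinase and a human CD2 surface reporter (hCD2), and recombined cells carry tdTomato. Cells were sorted as CD3- B220- CD11c+ MHC-II+ tdTomato+ and parted into an hCD2+ and an hCD2- fraction, where hCD2 is meant to mark cells with the cassette on at the sort and tdTomato alone cells with recombination at some earlier point. The same 12 mice, each under its own hashtag, gave both fractions. After filtering, 7099 hCD2+ cells held a median of 17486 UMIs, with 365 to 897 cells and 7269488 to 17966298 UMIs per mouse. The 4762 hCD2- cells held a median of 23846 UMIs, with 234 to 592 cells and 5914558 to 16238728 UMIs per mouse. Each fraction was 1 library, so that the fraction and its library preparation cannot be told apart in any comparison of fractions.

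The sort labels were held against the cassette's own transcripts. Gm38411 (ENSMUSG00000104669, annotated as an antisense gene) was at 41.0 ± 5.83 against 1.27 ± 0.392 CPM in hCD2+ and hCD2- cells (SD, n = 12 mice each; log2 5.0 ± 0.12, 12 of 12 mice). For hCD2 the levels were 38.1 ± 6.08 against 1.21 ± 0.589 CPM (5.0 ± 0.16, 12 of 12 mice). Droplets with 10 to 100 UMIs held 23.7 CPM of Gm38411 in the hCD2+ library, against 1.31 CPM in the hCD2- library. tdTomato, selected for in both fractions, was at 297 and 314 CPM.

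The first question was which cell types each fraction of the gate held. Prdm16 or Aire DC-like cells, a class known from markers such as Prdm16, Aire, Pigr and Trp63, made up 18.1% ± 4.23 of hCD2+ cells and 3.78% ± 1.01 of hCD2- cells (SD, n = 12 mice each; higher in 12 of 12, two-sided permutation p = 1e-05, adjusted p = 1.67e-05). ILC3 or LTi-like cells, innate lymphocytes of type 3, made up 42.2% ± 6.26 and 4.99% ± 2.06 (n = 12; higher in 12 of 12, adjusted p = 1.67e-05). The other dendritic cell classes went the opposite way: cDC2-like cells made up 2.12% ± 0.810 against 18.7% ± 4.49 and cDC1-like cells 1.32% ± 0.666 against 5.41% ± 2.17 (n = 12; lower in 12 of 12 for both classes, adjusted p = 1.67e-05). CCR7 migratory DC-like cells, which carry antigen from tissue to lymph nodes, made up 7.55% ± 2.98 against 19.4% ± 5.46 (n = 12, permutation p = 2e-05, adjusted p = 2.86e-05). Within this class cluster 0 was lower (4.72% ± 1.91 against 16.4% ± 5.30). Cluster 6 did not differ by the test (2.84% ± 1.16 against 2.97% ± 1.08, permutation p = 0.778). Cluster 25, left without a class though 9 of 10 CCR7 markers were elevated, was higher (2.98% against 0.164%). T cell-like cells, which a CD3- gate is meant to remove, still made up 3.94% ± 2.85 and 18.3% ± 4.52, and NK or ILC1-like cells 0.849% ± 0.464 and 9.43% ± 2.55 (n = 12, adjusted p = 1.67e-05 for both classes). For pDC-like cells the shares were 0.478% ± 0.451 and 2.13% ± 2.19 (n = 12; lower in 10 of 12, permutation p = 0.00094, adjusted p = 0.00117). Monocyte or macrophage-like cells were at 1.65% ± 1.21 and 1.02% ± 1.20 (n = 12, permutation p = 0.226; adjusted p = 0.226, and 0.0244 when signs were flipped within paired mice). Stromal cell-like cells were 8 of the hCD2+ cells and 0 of 4762 hCD2- cells. The smallest p these permutations can give is 1e-05, and the shares hold for this gate only.

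In the hCD2+ library the Prdm16 or Aire DC-like class was formed by clusters 24 (649 cells), 23 (323) and 10 (289), and in the hCD2- library almost wholly by cluster 10 (167 of 182 cells). The ILC3 or LTi-like class lay in clusters 4, 9, 5 and 18 in both libraries, and the CCR7 class in clusters 0 and 6, with 330 and 197 hCD2+ cells and 792 and 144 hCD2- cells. T cell-like cells came from clusters 3, 7 and 22. Clusters with no class held the remaining cells: clusters of low UMI count took 15.4% ± 2.97 of hCD2+ and 6.33% ± 2.01 of hCD2- cells, and clusters with dendritic and T cell markers together took 1.36% and 5.74% (n = 12). No cluster was named for B cells, plasma cells, neutrophils, mast cells or basophils, endothelial, epithelial or erythroid cells.

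**Figure D1:**
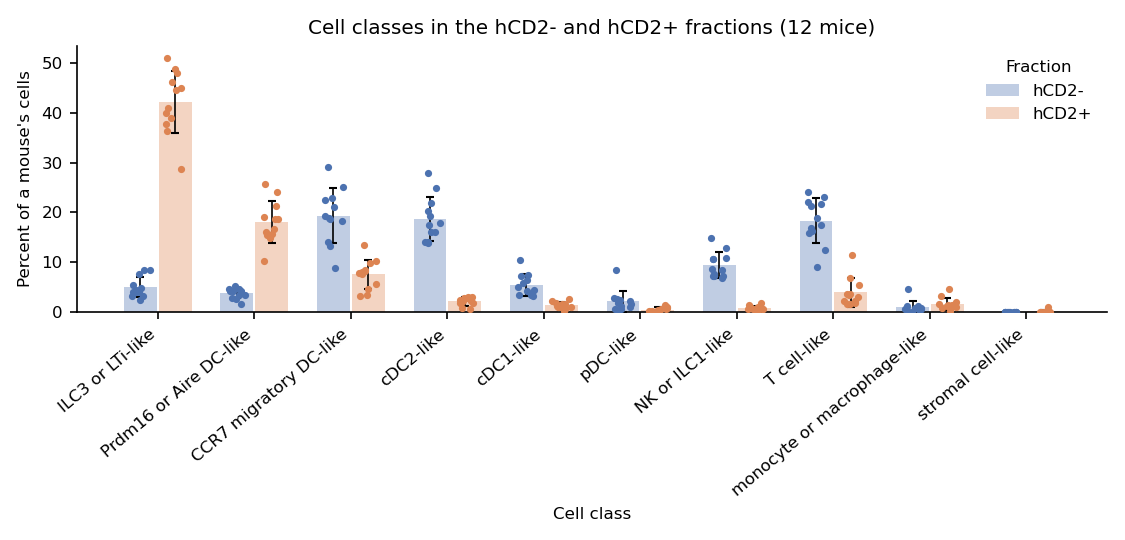
Share of each mouse's cells (percent) in 10 cell classes in the hCD2- and hCD2+ fractions; points are the 12 mice, bars their means and error bars SD. ILC3 or LTi-like cells average 42.2% of hCD2+ and 4.99% of hCD2- cells, and Prdm16 or Aire DC-like cells 18.1% and 3.78%.

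Which classes carry the cassette's transcript was the next question. In hCD2+ Prdm16 or Aire DC-like cells Gm38411 stood at 73.7 ± 5.70 CPM and in hCD2+ ILC3 or LTi-like cells at 55.3 ± 5.33 CPM (SD, n = 12 mice), against 1.5 ± 1.92 CPM in CCR7 migratory DC-like cells. With each cell thinned to 5000 UMIs, 27.0% of the 1177 Prdm16 or Aire DC-like cells had at least 1 Gm38411 UMI (95% Wilson interval 24.6% to 29.6%), as did 21.3% of the 3000 ILC3 or LTi-like cells (19.8% to 22.8%). For CCR7 cells the share was 0.596% (0.203% to 1.74%). Before thinning the median depths of these classes were, in the same order, 30829, 16695 and 31713 UMIs. No Gm38411 UMI was found in 92 thinned cDC1-like cells. In the hCD2- library 3.85% of 156 Prdm16 or Aire DC-like and 11.7% of 222 ILC3 or LTi-like cells had a Gm38411 UMI, against 0.565% of 885 CCR7 cells (median depths 24336, 18450 and 29567 UMIs). Intervals and floors cover counting error only.

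**Figure D2:**
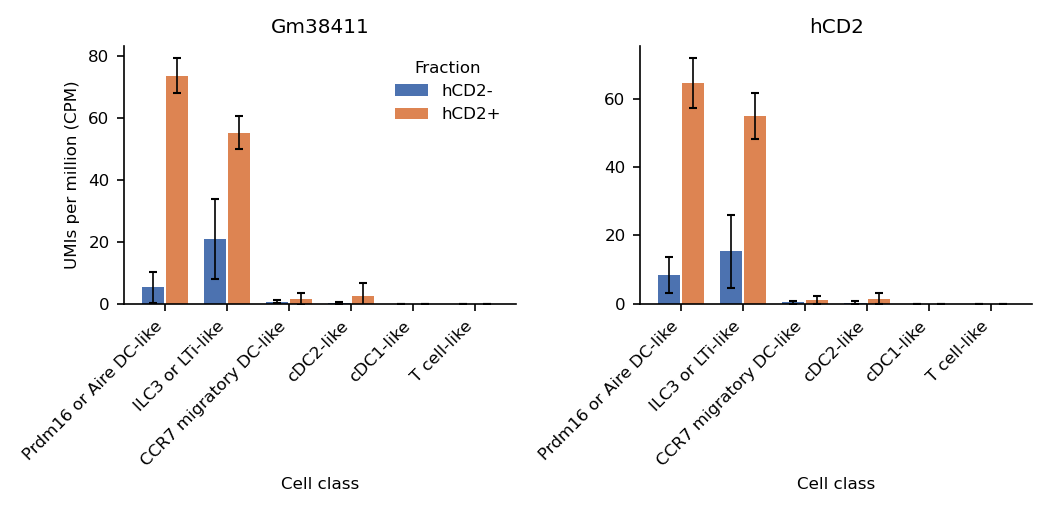
Mean CPM of Gm38411 and hCD2 by cell class and fraction; bars are means over mice with at least 10 cells of the class and error bars SD. Gm38411 is highest in hCD2+ Prdm16 or Aire DC-like cells (73.7 CPM) and hCD2+ ILC3 or LTi-like cells (55.3 CPM).

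Over all cells, the comparison of fractions asks what the sort on hCD2 separates. Prdm16, a zinc-finger transcription factor (ENSMUSG00000039410, chromosome 4, 154316125 to 154636873), was at 706 ± 211 against 9.71 ± 4.50 CPM (6.18 ± 0.23, 12 of 12 mice). Fabp1, a fatty acid carrier, was at 71.6 ± 23.7 against 0.379 ± 0.476 CPM (7.42 ± 0.29, 12 of 12 mice). Pigr, the polymeric immunoglobulin receptor, was higher (ratio 886, counting interval 303 to 4301) and Aire, which drives tissue antigen expression in the thymus, differed by 2.54 ± 0.21. Col17a1 (7.15 ± 0.20), Plekhs1 (5.94 ± 0.25), Prr29 (5.35 ± 0.15) and Tdh (4.95 ± 0.22) were also higher. Among the lower genes were the NK receptor genes Klra4 (-5.42 ± 0.48), Klre1 (-3.40 ± 0.30) and Klrc1 (-2.78 ± 0.32), with Eomes (-3.60 ± 0.24) and Xcl1 (-2.96 ± 0.44). edgeR called 8968 of 13236 genes, 4487 higher and 4481 lower. With cells drawn to the same cluster mix in both fractions, 1185 genes passed, and 13 of 28 named genes tested lost their call, among them Aire, Klre1, Klrc1 and Xcl1. That draw kept 1915 cells per fraction, so that mix and cell number changed together.

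By gene list (counts over all genes tested, members not counted were not called, and a count adjusted over the list alone is given where it differed), the type 3 lymphoid regulators went up: 13 of 14 rose and 1 fell (median log2 1.24, adjusted p = 2.54e-06, adjusted p = 0.0815 with an estimated correlation), with Rora (2.48 ± 0.12) and Il18r1 (2.30 ± 0.13) higher and Ahr, an aryl hydrocarbon receptor, at -0.73. For lymphotoxin and non-canonical NF-kB genes, 11 of 13 rose and 1 fell (median log2 0.45, adjusted p = 0.000670, adjusted p = 0.0815 with an estimated correlation), among them Ltb (1.72 ± 0.08), Lta (2.46 ± 0.16) and Tnfsf11 (2.70 ± 0.18). Central tolerance and epithelial-associated genes moved alike: 5 of 6 rose (median log2 2.73, adjusted p = 0.00545, adjusted p = 0.0815 with an estimated correlation), with Epcam (2.93 ± 0.12) and Cldn7 (7.02 ± 0.33). In retinoid metabolism 6 of 10 rose and 1 fell (median log2 0.71, adjusted p = 0.0238, adjusted p = 0.113 with an estimated correlation), among them Rarg (2.26 ± 0.10) and Dhrs9 (-2.22 ± 0.25). MHC class II presentation went the other way, where 10 of 15 fell and 1 rose (median log2 -0.20, adjusted p = 0.0238, adjusted p = 0.610 with an estimated correlation). Costimulation and checkpoint ligands followed: 7 of 13 fell and 3 rose (median log2 -0.69, adjusted p = 0.0265, adjusted p = 0.493 with an estimated correlation), with Cd86 (-1.72 ± 0.13) and Tnfsf4 (1.37 ± 0.25). Of the type I interferon response genes 11 of 16 fell and 1 rose (median log2 -0.75, adjusted p = 0.0265, adjusted p = 0.610 with an estimated correlation). In the proliferation list 9 of 15 fell (median log2 -0.46, adjusted p = 0.0238, adjusted p = 0.610 with an estimated correlation).

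The remaining 7 lists did not pass the list test in all cells. Treg induction and tolerance genes went both ways: 7 of 15 rose and 6 fell (median log2 0.21, adjusted p = 0.390), with Itgav (1.84 ± 0.10), Ido1 (2.16 ± 0.25) and Cd274 (-0.69 ± 0.15). Chemokines and receptors did too: 9 of 18 fell and 4 rose (median log2 -0.41, adjusted p = 0.291). Of the pattern recognition receptors 10 of 17 fell and 4 rose (median log2 -0.54, adjusted p = 0.122). For DC development factors 7 of 19 fell and 7 rose (8 and 7 adjusted over the list alone, median log2 -0.12, adjusted p = 0.618). For inflammatory cytokines 2 of 9 fell and 3 rose (median log2 0.02, adjusted p = 0.871, test down, mean log2 0.07). In MHC class I presentation 7 of 15 fell and 2 rose (6 and 2 adjusted over the list alone, median log2 -0.16, adjusted p = 0.129, blocked adjusted p = 0.0285). Among immediate early and heat shock genes 6 of 12 rose and 1 fell (median log2 0.50, adjusted p = 0.129). Of the genes always reported, Itgb8 (1.64 ± 0.26), Il7r (2.01 ± 0.09), Cd4 (1.38 ± 0.10) and Zbtb46 (0.36 ± 0.05) were higher, Ccr7 (-0.23 ± 0.10) and Flt3 (-0.96 ± 0.11) lower, and Aldh1a2 was not called (0.14 ± 0.14, adjusted p = 0.395). In the draw of equal cluster mixes Itgb8, Il7r, Cd4, Ccr7 and Flt3 lost their call and Zbtb46, a transcription factor of conventional DCs, turned to -0.22.

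The 3 clusters named Prdm16 or Aire DC-like differed from one another within the hCD2+ library, a comparison chosen after the clusters were seen. Cluster 23 held the most Aire, 610 CPM against 168 in cluster 10 and 18.1 in cluster 24, and cluster 24 the most Prdm16 (3336 CPM, against 1781 in cluster 23 and 174 in cluster 10) and Pigr (141, 1.72 and 0 CPM; n = 12 mice). These 3 genes are among the naming markers, though only Prdm16 was a clustering gene. Cluster 23 also had 6 of 10 markers of the CCR7 class elevated, against 5 of 10 of its own. Against cluster 24, cluster 23 had higher Phf24 (8.42 ± 0.26, 12 of 12 mice), Tnnt2 (6.77 ± 0.18, 12 of 12 mice) and Aqp4 (6.52 ± 0.29, 12 of 12 mice), where Aqp4 encodes a water channel. Ccr7, the receptor that guides cells to lymph nodes, and Itgb8, the integrin chain that activates TGF-beta, were higher too (3.05 ± 0.14, a clustering gene, and 3.33 ± 0.15), as was Aldh1a2, the enzyme that makes retinoic acid (2.32 ± 0.16). Lower in cluster 23 were Gm38411 (-1.53 ± 0.11) and Itgax (-4.28 ± 0.26). MHC class I presentation genes moved together: 13 of 15 rose (median log2 0.94, adjusted p = 2.71e-07, held with an estimated correlation), with Nlrc5 (3.56 ± 0.10) and H2-K1 (1.53 ± 0.05). Of lymphotoxin and non-canonical NF-kB genes 8 of 10 rose and 2 fell (median log2 1.05, adjusted p = 0.00755, held with an estimated correlation), among them Traf1 (1.96 ± 0.07) and Ltb (-2.55 ± 0.11). For the other 13 lists adjusted p ran from 0.0867 to 0.830, but with mouse as a block immediate early and heat shock (down, adjusted p = 0.0115) and proliferation (down, adjusted p = 0.0115) passed. edgeR called 5340 of 7862 genes, 2636 higher and 2704 lower, and 2125 after thinning to 5000 UMIs per cell.

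Against cluster 24, cluster 10 had higher Cd86 (4.60 ± 0.31, 12 of 12 mice), Cd80 (4.06 ± 0.18, 12 of 12 mice) and Cd200 (4.28 ± 0.14, 12 of 12 mice), Cd86 and Cd80 being ligands of CD28. Cd37 (6.25 ± 0.21) and Cd81 (4.98 ± 0.18), which encode tetraspanins, were higher as well. Prdm16 was lower (-4.28 ± 0.20, 174 ± 102 against 3336 ± 369 CPM, 12 of 12 mice, clustering gene). So were Gm38411 (-3.06 ± 0.17), Cldn7 (-7.29 ± 0.28) and Epcam (-5.11 ± 0.22), of which Cldn7 and Epcam belong to epithelial junctions. Pigr had 0 counts in cluster 10 (at least 324-fold lower). None of the 15 lists tested passed (adjusted p from 0.0573 to 0.981), but with mouse as a block immediate early and heat shock (down, adjusted p = 0.0195) passed. There were 5431 calls among 8328 genes in edgeR, 2824 higher and 2607 lower, and 2110 after thinning.

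**Figure D3:**
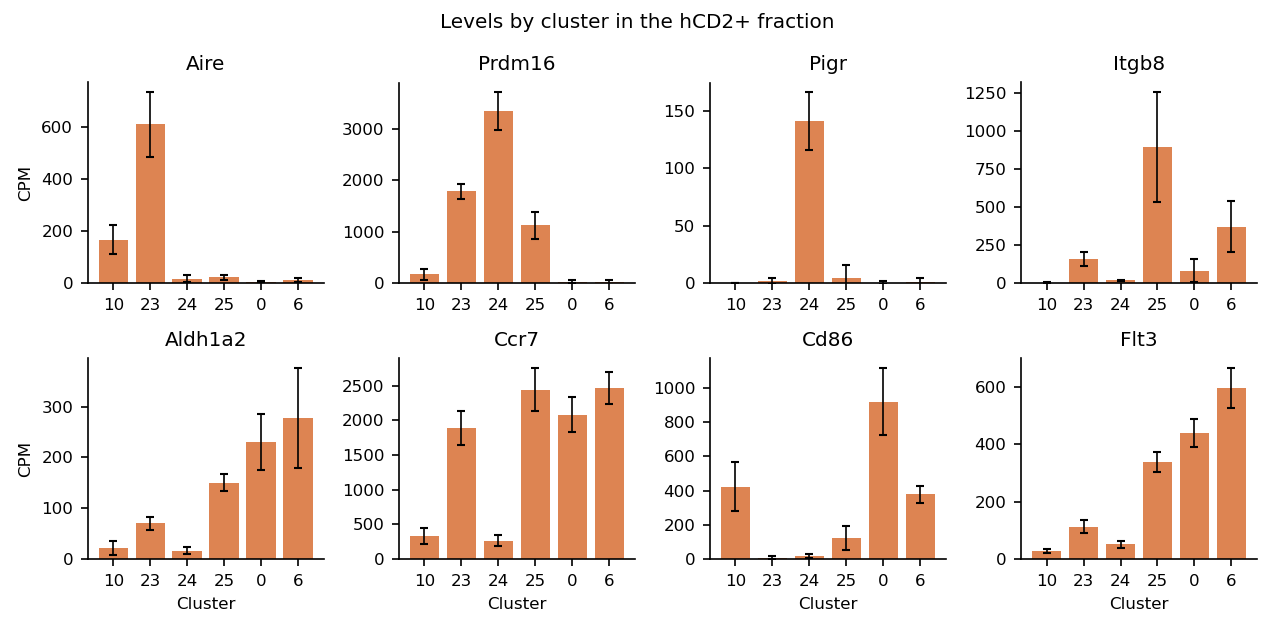
Mean CPM of 8 genes in clusters 10, 23 and 24 (Prdm16 or Aire DC-like), 25 (no class) and 0 and 6 (CCR7 migratory DC-like) of the hCD2+ library; bars are means over mice and error bars SD. Aire peaks in cluster 23 (610 CPM), Prdm16 and Pigr in cluster 24, and Itgb8 in cluster 25 (897 CPM).

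Setting Prdm16 or Aire DC-like cells against the other classes of the same library asks what marks them among cells that present antigen. Against cDC2-like cells of the hCD2+ library (n = 8 mice), Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610) was at 189 ± 35.2 against 0.765 ± 1.51 CPM (ratio 353, counting interval 97.6 to 2912, 8 of 8 mice). Itgb8 (ENSMUSG00000025321, chromosome 12, 119158022 to 119238802) was at 49.9 ± 17.6 against 1.65 ± 4.66 CPM (4.95 ± 0.55, 8 of 8 mice). Pigr (ENSMUSG00000026417, chromosome 1, 130826684 to 130852249) was at 83.1 ± 17.0 against 0.216 ± 0.611 CPM. Gm38411 (5.26 ± 0.34), Prdm16 (6.06 ± 0.38, clustering gene) and Ccr7 (2.27 ± 0.19, clustering gene) were higher too. Aire, Pigr, Prdm16 and Trp63 helped to name the class, so that their rise in this and the following class comparisons was partly given. The chemokine receptor gene Ccr2 (-6.48 ± 0.59), Havcr2 (-5.44 ± 0.28) and Cd86 (-3.26 ± 0.25) and Flt3, the growth factor receptor of dendritic cell precursors (-1.66 ± 0.15), were lower. Of lymphotoxin and non-canonical NF-kB genes 7 of 10 rose (7 and 1 adjusted over the list alone, median log2 1.0, adjusted p = 0.000301, adjusted p = 0.0953 with an estimated correlation), with Ltb (1.86 ± 0.12) and Tnfrsf11a (1.81 ± 0.18). In retinoid metabolism 5 of 7 rose (median log2 1.20, adjusted p = 0.0193, adjusted p = 0.0953 with an estimated correlation), among them Rarg (1.57 ± 0.18). Type 3 lymphoid regulators gave 9 rises and 3 falls among 13 genes (median log2 1.18, adjusted p = 0.0358, adjusted p = 0.254 with an estimated correlation, blocked adjusted p = 0.0802, adjusted p = 0.22 without naming markers). Within MHC class II presentation 9 of 15 fell and 2 rose (9 and 3 adjusted over the list alone, median log2 -0.41, adjusted p = 0.00813, adjusted p = 0.361 with an estimated correlation), with H2-Ob (-3.34 ± 0.20), H2-DMa (-1.76 ± 0.12) and H2-Eb2 (0.61 ± 0.14). Of proliferation genes 15 of 15 fell (median log2 -2.65, adjusted p = 7.44e-05, adjusted p = 0.237 with an estimated correlation), with Top2a (-2.69 ± 0.34) and Ccnb2 (-2.96 ± 0.37). Among chemokines and receptors 9 of 13 fell and 2 rose (median log2 -2.78, adjusted p = 0.0358, adjusted p = 0.225 with an estimated correlation), with Ccl9 (-3.42 ± 0.29), Ackr3 (6.52 ± 0.29) and Cxcl16 (1.98 ± 0.14). Another 8 lists did not pass (adjusted p from 0.147 to 0.922). edgeR called 4713 of 8797 genes, 2379 higher and 2334 lower, and 1705 after thinning.

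Against cDC1-like cells, which specialise in cross-presentation (n = 6 mice), Ackr3, a scavenging chemokine receptor, was at 233 ± 38.2 against 0 ± 0 CPM (at least 252-fold higher, 6 of 6 mice). Trp63 (at least 98.1-fold higher), Prr29 (at least 148-fold higher) and Lingo4 (at least 93.1-fold higher) were higher. Aldh1a2 (2.95 ± 0.32, 6 of 6 mice), Itgb8 (3.27 ± 0.47, 6 of 6 mice) and Ccr7 (4.40 ± 0.15, 6 of 6 mice, clustering gene) were higher as well, with Aldh1a2 (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243) at 28.1 ± 2.89 against 4.22 ± 3.09 CPM. Lower were Itga8 (at least 579-fold lower), Ccr2 (-7.20 ± 0.49), Havcr2 (-6.74 ± 0.20) and Cd36 (-6.65 ± 0.35). In retinoid metabolism 7 of 8 rose (median log2 2.70, adjusted p = 0.00303, held with an estimated correlation). Of lymphotoxin and non-canonical NF-kB genes 9 of 11 rose (median log2 2.03, adjusted p = 0.000347, held with an estimated correlation), with Relb (2.99 ± 0.14) and Ltb (4.02 ± 0.20). Type 3 lymphoid regulators gave 10 rises and 2 falls among 13 genes (median log2 1.55, adjusted p = 0.00458, adjusted p = 0.0729 with an estimated correlation), with Rora (4.56 ± 0.26) and Ahr (-2.13 ± 0.22). MHC class I presentation moved down: 9 of 15 fell and 4 rose (median log2 -0.54, adjusted p = 0.0312, adjusted p = 0.638 with an estimated correlation, blocked adjusted p = 0.0549), with Psmb9 (-1.83 ± 0.10), Pdia3 (-1.97 ± 0.11) and B2m (0.98 ± 0.10). For proliferation 15 of 15 fell (median log2 -2.68, adjusted p = 3.19e-05, adjusted p = 0.464 with an estimated correlation). The other 9 lists did not pass (adjusted p from 0.356 to 0.900). The 6032 calls among 9595 genes in edgeR, 3256 higher and 2776 lower, became 2093 after thinning.

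Against CCR7 migratory DC-like cells (n = 12 mice), the hCD2+ Prdm16 or Aire DC-like cells held less Aldh1a2, Itgb8, Ccr7 and Il12b and more Aire, Kit and Ltb. Aldh1a2 was at 30.1 ± 5.34 against 250 ± 55.8 CPM (-3.38 ± 0.12, 12 of 12 mice) and Itgb8 at 49.1 ± 15.8 against 208 ± 98.3 CPM (-2.41 ± 0.23, 11 of 12 mice). Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, a clustering gene) was at 644 ± 81.4 against 2238 ± 165 CPM (-2.11 ± 0.07). Il12b, a subunit of interleukin 12, was lower (-9.18 ± 0.40), with the chemokine genes Ccl5 (-8.53 ± 0.22) and Ccl17 (-6.59 ± 0.39) and the checkpoint ligand genes Cd274 (-4.06 ± 0.11) and Pdcd1lg2 (-6.22 ± 0.33). Higher were Aire (4.28 ± 0.17), Kit (3.71 ± 0.13) and Ltb (4.34 ± 0.17). So were Trp63 (ratio 470, counting interval 161 to 2281), Clic3 (ratio 654, counting interval 181 to 5400) and Bhmt (at least 271-fold higher). Of costimulation and checkpoint ligands 10 of 12 fell (median log2 -1.51, adjusted p = 8.32e-05, held with an estimated correlation), with Cd40 (-2.74 ± 0.09), Cd86 (-3.28 ± 0.15) and Cd70 (-6.65 ± 0.29). Of MHC class I presentation genes 14 of 15 fell (median log2 -1.52, adjusted p = 9.03e-09, held with an estimated correlation), with Psme1 (-2.05 ± 0.06) and H2-D1 (-1.52 ± 0.05). MHC class II presentation went up, where 10 of 15 rose and 3 fell (median log2 0.70, adjusted p = 0.0374, adjusted p = 0.306 with an estimated correlation), with H2-Oa (2.26 ± 0.10), H2-DMb1 (2.09 ± 0.10) and Lgmn (-2.46 ± 0.08). Inflammatory cytokines gave 6 falls among 7 genes (median log2 -1.78, adjusted p = 0.0456, adjusted p = 0.136 with an estimated correlation, adjusted p = 0.053 without naming markers). None of the other 10 lists passed (adjusted p from 0.0558 to 0.412), but with mouse as a block lymphotoxin and non-canonical NF-kB (down, adjusted p = 0.0460) passed. edgeR called 7386 of 9833 genes, 3997 higher and 3389 lower, and 3299 after thinning.

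Against ILC3 or LTi-like cells (n = 12 mice), the hCD2+ Prdm16 or Aire DC-like cells held more transcripts of most DC development factors and less of most type 3 lymphoid regulators, though both list tests were lost with an estimated correlation. Itgax, which encodes the CD11c of the gate, was at 85.0 ± 10.9 against 0.526 ± 0.302 CPM (7.43 ± 0.14, 12 of 12 mice), and Spi1, the myeloid factor PU.1, differed by 3.78 ± 0.08. Prdm16 (7.87 ± 0.12, clustering gene), Pigr (9.41 ± 0.21), Itgb8 (5.54 ± 0.26), Aldh1a2 (5.05 ± 0.18) and Flt3 (4.0 ± 0.15) were higher, while Gm38411 differed by 0.56 ± 0.05. Lower were Il7r, the interleukin 7 receptor chain (-3.92 ± 0.07, a clustering gene), Cd4 (-3.64 ± 0.13, clustering gene), Lta (-7.65 ± 0.19), Cxcr6 (-7.71 ± 0.21) and Cd160 (-7.44 ± 0.16). In MHC class II presentation 14 of 15 rose and 1 fell (median log2 1.17, adjusted p = 1.72e-06, adjusted p = 0.0574 with an estimated correlation). Costimulation and checkpoint ligands gave 8 rises and 2 falls among 11 genes (median log2 2.75, adjusted p = 0.0365, adjusted p = 0.0574 with an estimated correlation), with Cd40 (3.12 ± 0.11), Cd200 (3.96 ± 0.14) and Vsir (-2.52 ± 0.15). Of DC development factors 13 of 18 rose and 3 fell (median log2 0.62, adjusted p = 0.00634, adjusted p = 0.0574 with an estimated correlation). Of pattern recognition receptors 5 of 6 rose and 1 fell (median log2 2.66, adjusted p = 0.0486, adjusted p = 0.0913 with an estimated correlation, adjusted p = 0.054 without naming markers). Type 3 lymphoid regulators went down: 10 of 14 fell and 4 rose (median log2 -1.93, adjusted p = 0.00786, adjusted p = 0.0913 with an estimated correlation), with Rora (-3.22 ± 0.07) and Tox2 (-3.52 ± 0.09). No other list passed among 9 (adjusted p from 0.0578 to 0.896), but with mouse as a block MHC class I presentation (up, adjusted p = 0.0244), immediate early and heat shock (down, adjusted p = 0.0191) and proliferation (up, adjusted p = 0.0191) passed. There were 9083 calls among 11128 genes in edgeR, 4481 higher and 4602 lower, and 5656 after thinning. ILC3 or LTi-like cells came through a CD11c+ MHC-II+ gate with 0.526 ± 0.302 CPM of Itgax and 3878 ± 280 CPM of Cd74, where droplets of 10 to 100 UMIs held 28.6 and 3388 CPM.

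The same class comparisons in the hCD2- library ask whether Prdm16 or Aire DC-like cells that were tdTomato+ without hCD2, nearly all of cluster 10, stand apart in the same genes. Against cDC2-like cells (n = 9 mice), Aire (6.57 ± 0.35, 9 of 9 mice), Trp63 (6.32 ± 0.30, 9 of 9 mice), Chst1 (ratio 424, counting interval 144 to 2071, 9 of 9 mice) and Cd200 (5.05 ± 0.20, 9 of 9 mice) were higher. Itgax (-3.27 ± 0.20), Flt3 (-2.13 ± 0.22), Csf1r (ratio 0.00890, counting interval 0.000225 to 0.0498) and Ccl3 (ratio 0.00529, counting interval 0.000134 to 0.0296) were lower. Of MHC class II presentation genes 13 of 15 fell (median log2 -0.78, adjusted p = 7.12e-06, adjusted p = 0.0866 with an estimated correlation), with H2-Ab1 (-1.18 ± 0.06) and Cd74 (-0.74 ± 0.05). Pattern recognition receptors gave 5 falls among 5 genes (median log2 -2.04, adjusted p = 0.00851, adjusted p = 0.0866 with an estimated correlation). Type I interferon response genes gave 6 falls and 1 rise among 9 genes (6 and 2 adjusted over the list alone, median log2 -2.50, adjusted p = 0.0289, adjusted p = 0.412 with an estimated correlation). Among lymphotoxin and non-canonical NF-kB genes 7 of 10 rose and 2 fell (median log2 0.57, adjusted p = 0.0491, adjusted p = 0.118 with an estimated correlation, adjusted p = 0.062 without naming markers). Of type 3 lymphoid regulators 10 of 12 rose and 2 fell (median log2 1.54, adjusted p = 0.00851, adjusted p = 0.108 with an estimated correlation, adjusted p = 0.062 without naming markers). For the other 9 lists adjusted p ran from 0.0505 to 0.694, but with mouse as a block MHC class I presentation (down, adjusted p = 0.0414), chemokines and receptors (down, adjusted p = 0.00845), immediate early and heat shock (down, adjusted p = 0.00673) and proliferation (down, adjusted p = 0.0190) passed. edgeR called 4291 of 7984 genes, 2147 higher and 2144 lower, and 1526 after thinning.

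Against hCD2- cDC1-like cells (n = 8 mice), Aire (ratio 1499, counting interval 268 to 59298, 8 of 8 mice), Trp63 (ratio 1159, counting interval 207 to 45882, 8 of 8 mice) and Zeb2 (6.02 ± 0.23, 8 of 8 mice) were higher, as were Ccr7 (3.16 ± 0.48, clustering gene) and Igsf3 (ratio 582, counting interval 160 to 4822). Trpm2 (at least 75.1-fold lower), Cd36 (ratio 0.00170, counting interval 4.31e-05 to 0.00951) and Itga8 (ratio 0.00382, counting interval 9.67e-05 to 0.0214) were lower. Of lymphotoxin and non-canonical NF-kB genes 9 of 9 rose (median log2 1.75, adjusted p = 9.20e-05, held with an estimated correlation), with Relb (2.94 ± 0.13) and Ltb (2.75 ± 0.20). Of type 3 lymphoid regulators 8 of 10 rose and 2 fell (median log2 4.0, adjusted p = 0.0264, adjusted p = 0.170 with an estimated correlation, adjusted p = 0.073 without naming markers). In MHC class I presentation 12 of 15 fell and 1 rose (median log2 -0.89, adjusted p = 0.00196, adjusted p = 0.433 with an estimated correlation). Of proliferation genes 13 of 13 fell (median log2 -2.11, adjusted p = 0.00886, adjusted p = 0.487 with an estimated correlation). Another 10 lists did not pass (adjusted p from 0.0529 to 0.953), but with mouse as a block chemokines and receptors (down, adjusted p = 0.0164) passed. Of 6960 genes edgeR called 4540, 2295 higher and 2245 lower, and 1251 after thinning.

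Against hCD2- CCR7 migratory DC-like cells (n = 9 mice), Aldh1a2 (-3.52 ± 0.18, 9 of 9 mice), Itgb8 (-2.74 ± 0.50, 9 of 9 mice) and Ccr7 (-3.32 ± 0.20, 9 of 9 mice, clustering gene) were lower, as in the hCD2+ library. So were Il12b (-8.27 ± 0.70), Ccl5 (-6.97 ± 0.21) and Flt3 (-3.70 ± 0.23). Aire (3.33 ± 0.28), Kit (2.94 ± 0.17), Chst1 (at least 451-fold higher) and Il18r1 (6.21 ± 0.47) were higher. Of MHC class I presentation genes 13 of 15 fell and 2 rose (median log2 -1.69, adjusted p = 1.90e-07, adjusted p = 0.108 with an estimated correlation). Of DC development factors 12 of 18 fell and 5 rose (median log2 -1.0, adjusted p = 0.0266, adjusted p = 0.108 with an estimated correlation). Lymphotoxin and non-canonical NF-kB genes gave 8 falls and 1 rise among 9 genes (median log2 -0.73, adjusted p = 0.0266, adjusted p = 0.108 with an estimated correlation). Inflammatory cytokines gave 4 falls among 5 genes (median log2 -2.42, adjusted p = 0.0266, adjusted p = 0.108 with an estimated correlation). Chemokines and receptors gave 4 falls among 5 genes (median log2 -2.37, adjusted p = 0.0266, adjusted p = 0.108 with an estimated correlation). Type I interferon response genes gave 5 falls among 7 genes (median log2 -0.82, adjusted p = 0.0266, adjusted p = 0.248 with an estimated correlation). The other 8 lists did not pass (adjusted p from 0.234 to 0.971). There were 4418 calls among 6984 genes in edgeR, 2248 higher and 2170 lower, and 1463 after thinning.

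Against hCD2- ILC3 or LTi-like cells (n = 8 mice), Cd86 (6.66 ± 0.29, 8 of 8 mice), Cd200 (7.28 ± 0.38, 8 of 8 mice) and Trp63 (ratio 129, counting interval 43.7 to 626, 8 of 8 mice) were higher. Lower were Cxcr6 (ratio 0.00134, counting interval 3.39e-05 to 0.00750, 8 of 8 mice), Il7r (-4.21 ± 0.13, 8 of 8 mice, clustering gene) and Lta (-6.42 ± 0.60, 8 of 8 mice). Costimulation and checkpoint ligands gave 7 rises among 8 genes (median log2 3.14, adjusted p = 0.000158, held with an estimated correlation). MHC class II presentation gave 10 rises among 12 genes (median log2 1.17, adjusted p = 9.46e-06, adjusted p = 0.118 with an estimated correlation). Of type 3 lymphoid regulators 10 of 13 fell (median log2 -2.74, adjusted p = 9.46e-06, held with an estimated correlation), with Rora (-3.46 ± 0.20) and Tox (-3.73 ± 0.31). Of retinoid metabolism genes 3 of 3 fell (median log2 -2.24, adjusted p = 0.00249, held with an estimated correlation). Immediate early and heat shock genes gave 9 falls among 12 genes (median log2 -1.20, adjusted p = 0.00249, adjusted p = 0.346 with an estimated correlation), with Junb (-2.43 ± 0.09) and Ier2 (-2.45 ± 0.16). None of the other 8 lists passed (adjusted p from 0.171 to 0.913). edgeR called 2856 of 5559 genes, 1483 higher and 1373 lower, 907 after thinning and 1863 with at least 20 cells per mouse (only 2 against 2 mice).

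Within a class, hCD2+ and hCD2- cells were compared. In Prdm16 or Aire DC-like cells (12 hCD2+ and 9 hCD2- mice) the difference followed the clusters. The genes of cluster 24 were nearly absent from hCD2- cells: Pigr was at 82.5 ± 14 against 0 ± 0 CPM (at least 104-fold higher, 9 of 9 mice), with Grifin (at least 134-fold higher, clustering gene), Slc28a3 (at least 109-fold higher) and Bhmt (at least 63.9-fold higher). Prdm16 (4.46 ± 0.34, 9 of 9 mice, clustering gene) and Gm38411 (3.94 ± 0.22, 9 of 9 mice) were higher, as were Itgb8 (1.42 ± 0.36), Ccr7 (1.12 ± 0.18, clustering gene) and Aldh1a2 (0.81 ± 0.19). Aire did not differ by the test (182 ± 40.6 against 163 ± 86.9 CPM, 0.25 ± 0.20, adjusted p = 0.327). Lower in hCD2+ cells were Cd80 (-2.02 ± 0.11), Cd86 (-2.51 ± 0.18), Cd200 (-1.67 ± 0.13), Cd37 (-2.70 ± 0.15) and Kcnq5 (-3.13 ± 0.25, clustering gene). Retinoid metabolism genes gave 5 rises and 1 fall among 8 genes (6 and 1 adjusted over the list alone, median log2 0.89, adjusted p = 0.0155, adjusted p = 0.0944 with an estimated correlation), with Dhrs3 (4.28 ± 0.31). Of MHC class I presentation genes 11 of 15 rose (median log2 0.62, adjusted p = 0.000258, adjusted p = 0.325 with an estimated correlation). Of MHC class II presentation genes 9 of 15 rose and 5 fell (median log2 0.48, adjusted p = 0.0419, adjusted p = 0.377 with an estimated correlation). Costimulation and checkpoint ligands went down: 8 of 11 fell and 2 rose (median log2 -0.93, adjusted p = 0.0230, adjusted p = 0.0944 with an estimated correlation). For pattern recognition receptors 4 of 5 rose (median log2 1.33, adjusted p = 0.0230, adjusted p = 0.0944 with an estimated correlation). For central tolerance and epithelial-associated genes 3 of 5 rose (3 and 1 adjusted over the list alone, median log2 4.12, adjusted p = 0.0155, adjusted p = 0.0944 with an estimated correlation). No other list passed among 9 (adjusted p from 0.102 to 0.812), but with mouse as a block immediate early and heat shock (up, adjusted p = 0.0273) passed. edgeR called 5083 of 10318 genes, 2628 higher and 2455 lower, 1922 after thinning and 2012 with genes enriched in empty droplets left out.

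Cluster 10 alone, which both fractions held in like shares (4.13% ± 1.41 and 3.47% ± 1.07, n = 12; permutation p = 0.209, adjusted p = 0.234), allows the comparison of fractions within 1 of the 3 clusters, and was chosen after the clusters were seen. Ctnna3 (5.95 ± 0.52, 9 of 9 mice, clustering gene), Col17a1 (3.43 ± 0.33, 9 of 9 mice, clustering gene) and Prdm16 (2.42 ± 0.36, 9 of 9 mice, clustering gene) were higher in its hCD2+ cells, Col17a1 encoding a collagen of epithelial anchoring. So was Mpeg1 (2.57 ± 0.37, 9 of 9 mice, clustering gene). Ms4a6c (-1.40 ± 0.34, clustering gene), Tnfrsf13b (-1.23 ± 0.26) and Kcnq5 (-1.08 ± 0.25, clustering gene) were lower. For central tolerance and epithelial-associated genes 1 of 2 rose (2 adjusted over the list alone, median log2 0.72, adjusted p = 0.0150, adjusted p = 0.0540 with an estimated correlation), the called gene being Trp63 (0.92 ± 0.18). For the other 13 lists adjusted p ran from 0.175 to 0.718, but with mouse as a block chemokines and receptors (up, adjusted p = 0.00348) passed. There were 156 calls among 6581 genes in edgeR, 86 higher and 70 lower; 58 passed without genes enriched in empty droplets, 35 after thinning and 24 with at least 20 cells per mouse (only 9 against 2 mice). The droplets of 10 to 100 UMIs held more Prdm16 and Col17a1 in the hCD2+ library (321 against 5.16 CPM and 225 against 2.54 CPM), and there they lay above the levels in hCD2+ cells of cluster 10 (174 and 193 CPM), as did Mpeg1 (225 against 87.2 CPM in the cells).

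In CCR7 migratory DC-like cells (n = 12 mice each) hCD2+ cells held more Aldh1a2 and Itgb8, known for retinoic acid synthesis and TGF-beta activation. Aldh1a2 was at 250 ± 55.8 against 166 ± 24.5 CPM (0.60 ± 0.10, 12 of 12 mice) and Itgb8 at 208 ± 98.3 against 98.2 ± 58.5 CPM (1.07 ± 0.30, 10 of 12 mice). Pdcd1lg2 (0.89 ± 0.23), Tgfb2 (0.95 ± 0.31) and Il12b (0.88 ± 0.31) were higher, Pdcd1lg2 encoding the checkpoint ligand PD-L2. Cpne8 (1.87 ± 0.29, 12 of 12 mice, clustering gene), Prdm16 (1.91 ± 0.49, 11 of 12 mice, clustering gene), Grik3 (1.82 ± 0.14, 12 of 12 mice) and Met (1.37 ± 0.26, 11 of 12 mice) were also higher. In hCD2+ against hCD2- droplets of 10 to 100 UMIs Prdm16 was at 321 against 5.16 CPM, above its level in these cells (24.6 and 5.90 CPM) in the hCD2+ library, and Itgb8 at 92.6 against 21.5 CPM. With Gm38411 at 1.5 CPM in the hCD2+ cells, below the 23.7 CPM of those droplets, present activity of the cassette was not seen in this class. Lower were Dkk2 (-1.32 ± 0.37, 11 of 12 mice, clustering gene), Nod2 (-1.09 ± 0.19, 11 of 12 mice) and Wdfy4 (-1.13 ± 0.31, 9 of 12 mice, clustering gene). MHC class I presentation went up: 9 of 15 rose and 1 fell (11 and 1 adjusted over the list alone, median log2 0.23, adjusted p = 2.51e-05, held with an estimated correlation), with H2-K1 (0.41 ± 0.05). Class II presentation went down: 8 of 13 fell (median log2 -0.46, adjusted p = 3.36e-05, adjusted p = 0.0562 with an estimated correlation), with H2-Eb1 (-0.46 ± 0.08) and H2-Oa (-0.65 ± 0.12). Of DC development factors 10 of 18 fell (median log2 -0.24, adjusted p = 3.98e-05, held with an estimated correlation), with Zeb2 (-0.83 ± 0.13), Runx3 (-0.58 ± 0.11) and Itgax (-0.74 ± 0.15). Pattern recognition receptors gave 3 falls among 6 genes (5 adjusted over the list alone, median log2 -0.55, adjusted p = 0.0117, held with an estimated correlation). Lymphotoxin and non-canonical NF-kB genes gave 3 falls among 11 genes (median log2 -0.10, adjusted p = 0.0178, held with an estimated correlation). Another 10 lists did not pass (adjusted p from 0.173 to 0.905). edgeR called 1440 of 8052 genes, 768 higher and 672 lower; 675 passed without genes enriched in empty droplets and 593 after thinning. Hmga1 (-1.72 ± 0.15), Wdr89 (1.33 ± 0.09) and Ftl1-ps1 (1.70 ± 0.11) were among the genes that moved alike in most classes.

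The CCR7 class mixed clusters 0 and 6 in unlike parts, so cluster 0 was also compared alone (n = 12 mice each), a choice made after the clusters were seen. Itgb8 was at 83.1 ± 75.6 against 27.9 ± 17.8 CPM there (1.62 ± 0.39, 10 of 12 mice) and Aldh1a2 at 230 ± 54.4 against 156 ± 31.9 CPM (0.60 ± 0.12, 11 of 12 mice). Droplets of 10 to 100 UMIs held 92.6 against 21.5 CPM of Itgb8, so that this gene stood below them in the hCD2+ library. The chemokine genes Ccl22 (1.03 ± 0.15, clustering gene), Ccl17 (0.99 ± 0.29) and Cxcl1 (1.27 ± 0.33, clustering gene) and the protease inhibitor gene Serpinb9b (1.72 ± 0.40, clustering gene) were higher. Lower were Gpr65 (-1.14 ± 0.18), Ptpn22 (-1.25 ± 0.25) and Sema4d (-1.16 ± 0.25). Treg induction and tolerance gave 3 rises and 1 fall among 8 genes (4 and 1 adjusted over the list alone, median log2 0.31, adjusted p = 0.0572, blocked adjusted p = 0.00655). Costimulation and checkpoint ligands gave 2 rises among 11 genes (4 adjusted over the list alone, median log2 0.34, adjusted p = 0.0519, blocked adjusted p = 0.0168). For MHC class I presentation 5 of 15 rose (6 adjusted over the list alone, median log2 0.17, adjusted p = 0.00359, adjusted p = 0.210 with an estimated correlation). Of DC development factors 5 of 18 fell (9 adjusted over the list alone, median log2 -0.23, adjusted p = 2.52e-05, held with an estimated correlation). Among lymphotoxin and non-canonical NF-kB genes 2 of 10 fell (3 adjusted over the list alone, median log2 -0.16, adjusted p = 0.00874, adjusted p = 0.0613 with an estimated correlation). The other 9 lists did not pass (adjusted p from 0.10 to 0.974), but with mouse as a block immediate early and heat shock (down, adjusted p = 0.00503) passed. Of 7047 genes edgeR called 564, 315 higher and 249 lower; 271 passed without genes enriched in empty droplets and 306 after thinning.

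ILC3 or LTi-like cells (12 hCD2+ and 11 hCD2- mice) differed in fewer genes. The reporters moved with the sort: hCD2 was at 54.9 ± 6.78 against 15.4 ± 10.7 CPM (1.75 ± 0.19, 11 of 11 mice) and Gm38411 at 55.3 ± 5.33 against 20.8 ± 13 CPM (1.41 ± 0.17, 11 of 11 mice). Fstl4 (2.08 ± 0.40, 10 of 11 mice, clustering gene), Palld (1.52 ± 0.32, 11 of 11 mice, clustering gene) and Hopx (1.29 ± 0.32, 10 of 11 mice, clustering gene) were higher, as were Ahr (0.96 ± 0.18) and Id2 (0.39 ± 0.08), both regulators of ILC3. Ackr3 (-1.41 ± 0.22, 9 of 11 mice), Gimap4 (-1.11 ± 0.18, 10 of 11 mice, clustering gene) and Ms4a4b (-1.09 ± 0.15, 11 of 11 mice, clustering gene) were lower, as were Cd274 (-0.61 ± 0.15), Cd80 (-1.0 ± 0.27, blocked adjusted p = 0.0873), Zbtb46 (-0.30 ± 0.08) and Ifitm3 (-1.20 ± 0.27). MHC class I presentation gave 1 rise and 1 fall among 15 genes (median log2 0.09, adjusted p = 0.744, blocked adjusted p = 0.0148). None of the other 13 lists passed (adjusted p from 0.650 to 0.928). edgeR called 422 of 9888 genes, 177 higher and 245 lower, and 258 with mouse as a block in the paired fit; 180 passed without genes enriched in empty droplets and 133 after thinning. Wald tests in DESeq2 called 678.

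In cDC2-like cells (8 hCD2+ and 12 hCD2- mice) Retnla, Fn1 and Lyz2, all known from macrophages, were higher in hCD2+ cells. Proliferation genes were higher too, though their list test was lost with an estimated correlation. Retnla, a secreted protein of alternatively activated macrophages, was at 512 ± 578 against 17.8 ± 39.0 CPM (4.86 ± 0.90, 7 of 8 mice), and Fn1 (fibronectin) and Lyz2 (lysozyme) differed by 3.57 ± 0.81 and 2.69 ± 0.54. Tox (3.73 ± 0.46) and Il18r1 (3.36 ± 0.56) were higher, and stood at 516 and 589 CPM in hCD2+ droplets of 10 to 100 UMIs. Lower were St18 (-2.21 ± 0.48, 7 of 8 mice, clustering gene) and Dlc1 (-1.84 ± 0.30, 8 of 8 mice, clustering gene) and Ccl5 (-1.65 ± 0.21), Il12rb2 (-1.63 ± 0.25, clustering gene) and Cd86 (-0.54 ± 0.15). Of proliferation genes 10 of 15 rose (median log2 1.44, adjusted p = 1.34e-06, adjusted p = 0.285 with an estimated correlation), with Mki67 (1.44 ± 0.25), Cdk1 (1.99 ± 0.35) and Birc5 (1.71 ± 0.32). Chemokines and receptors gave 7 rises and 1 fall among 13 genes (8 and 3 adjusted over the list alone, median log2 1.40, adjusted p = 0.0214, adjusted p = 0.285 with an estimated correlation), with Ccl9 (2.38 ± 0.36) and Ccl6 (2.0 ± 0.35). Type I interferon response went down as a list with no gene called: 0 of 16 fell (4 adjusted over the list alone, median log2 -0.23, adjusted p = 0.00857, adjusted p = 0.511 with an estimated correlation). No other list passed among 11 (adjusted p from 0.0639 to 0.991), but with mouse as a block pattern recognition receptors (down, adjusted p = 0.0342) passed. edgeR called 996 of 8924 genes, 554 higher and 442 lower, and 552 in the paired fit with mouse as a block; 449 passed without genes enriched in empty droplets and 244 after thinning.

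In T cell-like cells (9 hCD2+ and 12 hCD2- mice) Ddah1 (1.39 ± 0.23, 8 of 9 mice), Wdr89 (1.27 ± 0.08, 9 of 9 mice) and Nutf2-ps1 (1.24 ± 0.19, 9 of 9 mice) were higher. Lower were Gstp1 (-3.14 ± 0.30, 9 of 9 mice) and Polr2l (-1.47 ± 0.22, 9 of 9 mice). B2m, the light chain of MHC class I, differed by 0.26 ± 0.05. For MHC class I presentation 1 of 15 rose (2 adjusted over the list alone, median log2 0.09, adjusted p = 0.0479, adjusted p = 0.937 with an estimated correlation, blocked adjusted p = 0.0971). For MHC class II presentation 0 of 7 fell (median log2 -0.19, adjusted p = 0.0479, adjusted p = 0.937 with an estimated correlation, blocked adjusted p = 0.875). For the other 11 lists adjusted p ran from 0.138 to 0.985, but with mouse as a block proliferation (up, adjusted p = 0.0391) passed. There were 94 calls among 7403 genes in edgeR, 52 higher and 42 lower, and 59 after thinning. At clustering resolution 0.5, which draws the class anew, 3681 of 9293 passed, and Focad and Il7r turned (-0.31 and -0.66). There the class took in a cluster with 4 of 8 T cell markers and Top2a and Kif11 among its 10 genes of largest fold. That cluster gave 108 of the 427 hCD2+ and 104 of the 1113 hCD2- cells of the class, so that the mix of cells changed too. In cDC1-like cells (6 and 11 mice) Ctla4 (1.68 ± 0.31, 5 of 6 mice, clustering gene, blocked adjusted p = 0.266) was higher, and Gstp1 (-2.19 ± 0.31, 6 of 6 mice), Hmga1 (-1.74 ± 0.25, 6 of 6 mice) and tdTomato (-1.42 ± 0.28, 6 of 6 mice) were lower. Gstp1, Hmga1, tdTomato, Atp5k, Cmss1 and Wdr89 were named by the rule for large changes in T cell-like cells too. None of the 14 lists tested passed (adjusted p from 0.0638 to 0.848). edgeR called 42 of 7401 genes, 12 higher and 30 lower, and 25 in the paired fit with mouse as a block; 26 passed without genes enriched in empty droplets, 13 after thinning and 66 by DESeq2 Wald tests.

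Dividing cells were counted as cells with UMIs of at least 2 of 6 cell cycle genes after thinning. Cluster 12 (90 hCD2+ and 79 hCD2- cells), with Hist1h1b, Rrm2 and Kif11 among its 10 genes of largest fold, had no class. Its cells are therefore missing from every class share given here. Among cDC2-like cells 27.0% ± 15.6 of hCD2+ cells (7 mice) and 13.6% ± 3.38 of hCD2- cells (12 mice) divided (exact permutation p = 0.00709, adjusted p = 0.0215; higher in 5 of 7 mice, adjusted p = 0.188 when signs were flipped within paired mice). For T cell-like cells the shares were 9.40% ± 3.38 (9 mice) and 5.94% ± 1.83 (12 mice; exact permutation p = 0.00718, adjusted p = 0.0215; higher in 7 of 9, and 0.164 with flipped signs). ILC3 or LTi-like cells were at 0.638% ± 0.554 (12 mice) and 0 of 222 cells (11 mice, upper 95% Wilson limit 1.70%), and no test is given for them, since at the pooled share 1.31 dividing cells would be expected among the 222. The share was 4.62% ± 2.09 and 6.48% ± 7.41 in Prdm16 or Aire DC-like cells (exact permutation p = 0.447, adjusted p = 0.875). CCR7 migratory DC-like cells (3.62% ± 4.32 and 3.10% ± 2.10, permutation p = 0.729, n = 12) and cDC1-like cells (28.0% ± 16.1 and 24.3% ± 12.3, exact permutation p = 0.621) did not differ by the test either. In droplets of 10 to 100 UMIs Mki67 was at 72.3 CPM (hCD2+) against 130 CPM (hCD2-). At 1 gene or without thinning neither of the called classes passed, and at 3 genes cDC2-like cells alone did.

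Whether hCD2 goes with different changes in ILC3 or LTi-like and CCR7 migratory DC-like cells was tested by an interaction term, the effect in the former minus that in the latter. edgeR called 427 of 10181 genes, 282 above 0 and 145 below. Antigen presentation genes of class II were above 0 in 4 of 14 measured members (H2-Aa 0.37 ± 0.11, H2-Ab1 0.43 ± 0.12, H2-Eb1 0.45 ± 0.11, H2-Oa 0.67 ± 0.14). In the type 3 lymphoid regulators 2 of 14 were above 0 (Ahr 1.18 ± 0.26, Id2 0.36 ± 0.10) and 2 below. Ptgs2, a prostaglandin synthase, was at 2.90 ± 0.79 and Pdcd1lg2 at -1.12 ± 0.33. The balance of directions depended on the scaling: 66.0% of calls were above 0 with TMM and 32.0% with DESeq2 size factors. The median term of all genes was 0.06 and -0.03. With DESeq2 size factors H2-Aa, H2-Ab1, H2-Eb1 and Id2 were not called, so no direction is given for the MHC class II list.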

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

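All tests of explanations in this part were chosen only after the results were seen; the interaction test and the comparison with other splits were planned.

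The change with hCD2 differed between ILC3 or LTi-like and CCR7 migratory DC-like cells in 427 genes. Of those named by the rule, the term (ILC3 effect minus CCR7 effect, log2) was above 0 for Apba1 (3.29), Ptgs2 (2.90), Aif1 (2.85), Pld4 (2.71), Pold1 (1.96), Zfp831 (1.76), Palld (1.56), Gadd45g (1.45), Zeb2 (1.37) and Ms4a6b (1.36). It was below 0 for Gucy1a1 (-4.27), Mapk10 (-2.50), Maf (-2.41), Cntn1 (-2.12), Il18r1 (-1.99), Nos1ap (-1.96), Camk4 (-1.87), Nebl (-1.75, blocked adjusted p = 0.0671), Lingo2 (-1.63), Serpinb1a (-1.47, blocked adjusted p = 0.0954) and Flt3 (-1.26). In the class that held less of the gene, 6 of them (Apba1, Pold1, Palld, Zeb2, Nos1ap and Serpinb1a) changed by more than free RNA could give, beyond 2 SE. The others did not, among them Il18r1 (589 against 104 CPM in hCD2+ against hCD2- droplets of 10 to 100 UMIs) and Maf (110 against 19.6 CPM). In 1 of 10 groups of 4 to 10 mice 1 mouse stood apart from the rest, where about 5% do so by chance: mouse 2 for Gm38411 in hCD2+ cDC2-like cells (12.1 CPM, others 0 to 5.19). Cells outside the comparisons also held Gm38411 in the hCD2+ library, at 29.8 CPM in Blank, 28.6 CPM in Multiplet and 26.7 CPM in Unassigned cells.

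The first pattern is a set of 70 genes (30 higher and 40 lower in hCD2+ cells, 25 of them ribosomal or mitochondrial) called alike in at least 4 of 6 classes. After thinning 49 were still called alike in at least 2 classes. Thinning keeps each gene's share of a cell's UMIs on average, so that it cannot exclude a bias tied to depth. The hCD2+ median depth was lower in ILC3 or LTi-like (16695 against 18450 UMIs) and T cell-like cells (15251 against 17446). It was higher in CCR7 migratory DC-like (31713 against 29567), Prdm16 or Aire DC-like (30829 against 24336) and cDC2-like cells (28366 against 27384.5). Lower depth was thus not common to the classes. Free RNA is excluded as its whole cause, although 81.4% moved the same way as the empty droplets: 64.9% of their 348 calls changed by more, beyond 2 SE, than free RNA could give at its largest share in the class. In cDC1-like cells, where that share was not bounded, 0 of 36 calls did, and in cDC2-like cells 17 of 64, so that a part in free RNA stays open there. Preparation of each fraction as 1 library may be the source, and with 1 library per fraction it cannot be told apart from the sort. A common biological effect of recent cassette activity stays open and untested.

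The second pattern is the T cell-like cells in a gate on CD3- CD11c+ MHC-II+ cells. Droplets holding a T cell and a dendritic cell are excluded as the source of the T cell-like class, since its Cd74 was 1.37% of that of cDC2-like cells in the hCD2- library, and its median depth lower (17446 against 27384.5 UMIs). For the unnamed clusters 13, 16 and 20, with markers of both types, such droplets are a candidate source: their median of 48048 UMIs was 102% of the summed medians of T cell-like and CCR7 migratory DC-like cells. How T cell-like cells passed the gate was not tested.

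The third pattern is the lower Gm38411 in hCD2- than in hCD2+ ILC3 or LTi-like cells (20.8 against 55.3 CPM). Free RNA of the hCD2+ library is excluded as its whole source: the hCD2+ cells held 2.34 times the level of that library's empty droplets, and free RNA cannot lift cells above its own level. hCD2+ cells that fell into the wrong gate, selection by the gate on hCD2 itself and a lower activity of the cassette may each give this pattern and stay open, untested.

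In each of the 22 fits the real split of the mice called more genes than the other 30 splits drawn (1 of 31). For the 10 fits of hCD2+ against hCD2- cells, the interaction among them, an arbitrary grouping is thereby excluded. The other 12 compare classes or clusters that were made from expression, so that their outcome was given and decides nothing. The real count and the highest other were 8968 and 7598 for all cells, 1440 and 690 for CCR7, 422 and 3 for ILC3, 5083 and 688 for Prdm16 or Aire DC, 94 and 1 for T cell, 996 and 598 for cDC2 and 42 and 3 for cDC1-like cells. Prdm16 or Aire DC-like cells in the hCD2+ library gave 4713 and 2054 against cDC2, 6032 and 0 against cDC1, 7386 and 6498 against CCR7 and 9083 and 8294 against ILC3-like cells. In the hCD2- library these were 4291 and 0, 4540 and 2771, 4418 and 1, and 2856 and 1681. Cluster comparisons gave 3259 and 1635 (25 against CCR7), 5516 and 3773 (25 against 24), 5340 and 4556 (23 against 24), 5431 and 4555 (10 against 24), 156 and 0 (cluster 10) and 564 and 107 (cluster 0), and the interaction 427 and 8. Splits that called more than 8 genes all swapped the arms within 1 or 2 mice, and those that swapped more called at most 6. Among the 22 splits that part every pair the median count was 0 or 1 in edgeR, and among the 8 others the highest was 3.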

How the results depend on the processing

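The automatic doublet replacement, the mixed clusters, the low-UMI clusters, the lists without naming markers and the comparisons of single clusters were chosen only after the data were seen. Of 350 alternative values of counts, shares and levels 298 kept their direction and their side of the threshold (counts within 1.5 times), 44 moved, 6 weakened, 1 strengthened and 1 turned. For gene lists these were 281 of 382, with 77 weaker, 23 stronger and 1 moved, and for single named genes 5954 of 6099, with 107 weaker, 34 stronger and 4 turned. Unless said otherwise the cause was not tested, and adjusted p are those of edgeR or of permutation tests.

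Thinning to 5000 UMIs, which leaves fewer counts and cells, gave 593 genes for CCR7, 133 for ILC3, 1922 for Prdm16 or Aire DC, 59 for T cell, 244 for cDC2 and 13 for cDC1-like cells between fractions, 306 for cluster 0 and 35 for cluster 10. Prdm16 or Aire DC-like cells in the hCD2+ and hCD2- libraries gave 3299 and 1463 against CCR7, 5656 and 907 against ILC3, 2093 and 1251 against cDC1 and 1705 and 1526 against cDC2-like cells. Cluster comparisons gave 2110 (10 against 24), 2125 (23 against 24), 991 (25 against CCR7) and 1966 (25 against 24). Gm38411 in all hCD2- cells went from 1.27 to 2.05 CPM.

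Leaving out genes enriched in empty droplets, which tests fewer genes, gave 675 for CCR7, 180 for ILC3, 2012 for Prdm16 or Aire DC, 26 for cDC1, 449 for cDC2, 271 for cluster 0 and 58 for cluster 10. With no low-count filter the hCD2- comparisons of Prdm16 or Aire DC-like cells gave 7577 (CCR7), 5093 (ILC3), 7645 (cDC1) and 7043 (cDC2), the clusters 8355 (10 against 24) and 8134 (23 against 24), and the interaction 881. Mouse as a block gave 258 for ILC3, 25 for cDC1 and 552 for cDC2, and changed no other count by more than 1.5 times. At least 20 cells per mouse gave 1863 for Prdm16 or Aire DC against ILC3-like hCD2- cells on only 2 against 2 mice, and 24 for cluster 10 on only 9 against 2, both under the 3 mice per arm set for the comparisons, and left fewer than 2 in an arm to fit cDC2 or cDC1 between fractions or Prdm16 or Aire DC against either in the hCD2+ library. DESeq2 Wald tests gave 678 for ILC3 and 66 for cDC1-like cells.

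Equal cluster mixes, drawn with 1915 cells per fraction, gave 1185 genes for all cells, ended the call of 13 of 28 named genes tested and turned Zbtb46 from 0.36 to -0.22. Resolution 0.5, at which a cluster led by cell cycle genes joined the class, gave 3681 genes for T cell-like cells and turned Focad (-0.31) and Il7r (-0.66) there. Resolution 1.5 turned Il7r in Prdm16 or Aire DC against cDC2-like hCD2+ cells (-0.13). Of 219 list tests 72 passed, 8 of them for central tolerance and epithelial-associated genes between classes, and 15 with an estimated correlation. Without naming markers that list could not be tested between classes, and type 3 lymphoid regulators lost their call in 3 class comparisons.

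The differences in dividing cells (percentage points, hCD2+ minus hCD2-) were 3.46 for T cell and 13.4 for cDC2-like cells. At 1 of 6 genes they were -2.75 and 7.65 (adjusted p = 0.414 each by permutation), and at 3 genes 3.15 for T cell-like cells (adjusted p = 0.0570 by permutation). Without thinning they were 2.41 and 15.2 (adjusted p = 0.671 and 0.0552 by permutation). Flipping signs within paired mice gave adjusted p = 0.164 for 3.46 (T cell) and 0.188 for 13.4 (cDC2) by permutation, and 0.0244 for the monocyte or macrophage share difference of 0.629. Depth limits the rare classes: shares of 0 are upper limits, and classes with under 10 cells in most mice could not be fitted.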

Other observations

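The comparisons of cluster 25 were chosen after it was seen. It had 9 of 10 CCR7 markers elevated, but got no class since only the epithelial marker Epcam was among its 10 genes of largest fold. It held 218 hCD2+ cells (2.98% ± 1.42, against 0.164% of hCD2- cells, n = 12) and stood between cluster 24 and the CCR7 migratory DC-like class in several genes. Its Itgb8, at 897 ± 361 against 220 ± 104 CPM in the CCR7 class (n = 8 mice; 1.99 ± 0.29, 8 of 8 mice), was the highest among clusters 0, 6, 10, 23, 24 and 25. Ccr7 was at 2444 ± 312 against 2253 ± 183 CPM (0.07 ± 0.08, adjusted p = 0.472, a clustering gene). Ackr3 (7.0 ± 0.43), Epcam (4.81 ± 0.26), Ido1 (4.26 ± 0.44), Prdm16 (5.23 ± 0.40, clustering gene), Gm38411 (4.0 ± 0.42) and Kit (2.10 ± 0.17) were higher than in the CCR7 class, where Ido1 breaks down tryptophan. Aldh1a2, the retinoic acid enzyme, was lower (-0.83 ± 0.13), as were Il12b (-8.09 ± 0.59), Cd86 (-2.50 ± 0.27), Ccl5 (-2.23 ± 0.19) and Cd81 (-5.65 ± 0.32). In MHC class I presentation 12 of 15 fell and 1 rose (13 and 2 adjusted over the list alone, median log2 -0.41, adjusted p = 0.000646, adjusted p = 0.217 with an estimated correlation). None of the other 12 lists passed (adjusted p from 0.0565 to 0.942). edgeR called 3259 of 6851 genes, 1646 higher and 1613 lower.

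Against cluster 24 (n = 8 mice), cluster 25 had higher Itgb8 (5.83 ± 0.25, 8 of 8 mice), Aldh1a2 (3.47 ± 0.16, 8 of 8 mice) and Flt3 (2.92 ± 0.10, 8 of 8 mice), with Ccr7 (3.30 ± 0.16, clustering gene), Ccl5 (7.42 ± 0.27), Cd36 (7.5 ± 0.33) and Scube3 (ratio 427, counting interval 145 to 2077). Lower were Pigr (-4.28 ± 0.46), Gm38411 (-2.15 ± 0.14), Prdm16 (-1.23 ± 0.11, clustering gene) and Cldn7 (-6.91 ± 0.28). Of Treg induction and tolerance genes 8 of 10 rose and 1 fell (median log2 2.91, adjusted p = 0.00718, adjusted p = 0.0587 with an estimated correlation), with Itgav (3.2 ± 0.14), Cd274 (2.80 ± 0.15) and Tgfb1 (-1.78 ± 0.13). Costimulation and checkpoint ligands gave 7 rises and 1 fall among 9 genes (8 and 1 adjusted over the list alone, median log2 1.57, adjusted p = 0.0183, adjusted p = 0.143 with an estimated correlation). MHC class I presentation gave 13 rises and 1 fall among 15 genes (median log2 1.19, adjusted p = 4.18e-06, adjusted p = 0.142 with an estimated correlation). Of lymphotoxin and non-canonical NF-kB genes 7 of 10 rose and 1 fell (median log2 0.78, adjusted p = 0.0269, adjusted p = 0.105 with an estimated correlation). Of proliferation genes 7 of 7 fell (median log2 -1.70, adjusted p = 0.0369, adjusted p = 0.383 with an estimated correlation). No other list passed among 10 (adjusted p from 0.0969 to 0.970), but with mouse as a block immediate early and heat shock (down, adjusted p = 0.0280) passed. edgeR called 5516 of 8332 genes, 2633 higher and 2883 lower.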
